A study of Homo sapiens with 6 samples.

How the data were processed

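Polyadenylated RNA from OCI-AML2 cells was sequenced on a NovaSeq instrument, per the labels' protocols. They name the RNeasy kit for extraction and a stranded mRNA kit for the libraries. The deposited table holds 1 column of read counts per library for 58233 Ensembl gene identifiers, and the authors' values were used as deposited, as whole numbers with no scaling. Trimmomatic, STAR and the genome build GRCh38 are named in the submitters' processing notes, without versions. The read counter, the strand setting of the counting and the annotation release are not given in the sources used here, so values of genes that share exon positions with another gene are uncertain. Of the genes named, RAB13, RHEX, LRG1, MCL1, BCL2L2, MDM2, HOXA9, CLDN7 and HLA-C share them on the same strand. Those with overlaps on the opposite strand only are IKZF1, IKZF5, CALHM2, LPO, WLS, CD82, THBS1, CALR, HDAC2, RBBP7, CCNA2, CDKN1A, CCND3, CDK4, CDK6, PLK1, BCL2L1, BCL2L11, BNIP3L, MYB, FLI1, MEF2C, NRP1, SPARC, ACTA2, IRF1, DUSP6, NDUFA2, FDPS, HYOU1 and HSP90AA1. The table has 0 columns of other samples. Each column was assigned to a sample by the library name that its label gives, and each sample to NT control or IKZF1-ko by its title. Of the identifiers, 57895 were found in GENCODE release 29, which gave positions on GRCh38, and 57392 had a symbol in the gene name table.

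Total counts per library ranged from 11300519 to 18214328. The filterByExpr function of edgeR, by group, kept 13028 genes, which held 99.9% of all counts. Log2 CPM values used TMM factors and a prior count of 2, and CPM values in the text are means ± SD over 3 libraries. The floor of 3 counts for a gene with no counts covers counting error only. The planned test, chosen with its alternatives before the data were examined, was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic.

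After the counts had been examined, a term was added for the library set, defined by the sign of the first principal component, which separates NT control replicate 2 and IKZF1-ko replicate 1 from the other 4 libraries in both groups. Because that term was defined from the same counts, its p-values take the sets as known and leave out the uncertainty of choosing them. The fit on the 4 libraries alone, the fit with 1 surrogate variable from sva 3.50.0, limma-voom with sample quality weights, the interaction of set and group and the dendritic cell list without CLEC10A were also added after that. The libraries of the 2 sets were not tested against each other.

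Gene lists, 39 in all with 775 different genes, were written from the study's labels and general knowledge of blood cells and cell stress. Lists with at least 5 tested members, 35 of them, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Lists with fewer members are described by gene only.

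Genes are named by a rule: IKZF1, the 12 highest and 12 lowest fold changes among genes past the threshold with a mean of at least 5 CPM in the higher group, non-overlapping groups and an official symbol, any measured member of the Ikaros, G1 control and BCL2 family lists, and up to 4 members of each other list by lowest adjusted p or, where none passes, by highest CPM. The rule was written for the planned fit. As that fit called 0 genes, the rule was applied to the fit with the library-set term, a choice made after the values were seen, and 487 genes met the criteria for naming by fold. NCF1B and NCF1C are named only as copies of NCF1.

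The alternatives were RLE, upper-quartile and library-size scaling, no filter on low counts or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, glmTreat against a fold of 1.5, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.

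The tests were checked on simulated counts for the same 13028 genes with 200 genes changed, for IKZF1-ko against NT control. On group alone the test recovered 0% of genes changed 1.25-fold, 0% of those changed 1.5-fold, 26% of those changed 2-fold and 68% of those changed 4-fold, with 0 false calls among 47. With the library-set term it recovered 42%, 78%, 88% and 98%, with 5 false calls among 158. With no gene changed, both fits called 0 genes. Camera found a simulated raised list and called 0 of 35 unchanged lists. Genes were simulated as independent of each other and with the library sets taken as true. The check therefore does not cover correlated genes within a list, or groups that differ in position along the difference between the sets. Among other splits of the real libraries, camera with the library-set term called up to 11 lists.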

Results

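Messenger RNA was measured in OCI-AML2, an established human cell line derived from acute myeloid leukemia, after CRISPR editing. The series had 1 comparison: 3 libraries labelled IKZF1-ko, from cells in which IKZF1 was targeted, against 3 libraries labelled NT control, from cells that received a non-targeting guide. IKZF1 encodes Ikaros, a zinc-finger transcription factor of blood cells. The comparison was set up to find genes whose expression goes with loss of IKZF1, in a study of palbociclib, an inhibitor of CDK4 and CDK6, and of resistance to the BCL2 inhibitor venetoclax. The 6 libraries held 11300519 to 18214328 counted reads each. The NT control libraries had 11699047, 14983528 and 11300519 counts in replicates 1, 2 and 3, and the IKZF1-ko libraries had 15250588, 18214328 and 16751839. A count was present for 17640 to 18860 genes per library, and 13028 genes passed the filter on low counts and were tested. The series design names 3 lines per group, whereas the extraction protocol speaks of parental and knockout cells in triplicate. Whether the replicates were separate edited lines, separate cultures or repeat extractions is therefore unclear, and p-values measure the spread between these libraries, which may be technical.

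The targeted gene was examined first. IKZF1 (ENSG00000185811, GRCh38 chromosome 7, 50304068 to 50405101) was present at 331 CPM (counts scaled to library size), 292 CPM and 334 CPM in NT control replicates 1, 2 and 3. In the libraries labelled IKZF1-ko it was present at 421 CPM, 426 CPM and 436 CPM. IKZF1 mRNA was therefore not lower in any of the libraries labelled IKZF1-ko, and the group means were 318.9 ± 23.8 CPM in NT control and 427.8 ± 7.66 CPM in IKZF1-ko (SD, n = 3 each). The log2 fold change was 0.42 (SE 0.099) with an edgeR adjusted p of 0.61 in the fit on group alone, and 0.43 (SE 0.047, adjusted p = 1.23e-05) in the fit with a library-set term described next. IKZF1 shares exon positions with a gene on the opposite strand. Counts per gene do not show an edited sequence or the protein, so this value does not check the labels, and all directions given here are those of the libraries so labelled. Of the other Ikaros family genes, IKZF4 (log2 fold change 0.13, adjusted p = 0.46) and IKZF5 (-0.08, adjusted p = 0.49) did not pass the test.

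Within libraries of like overall expression, the libraries labelled IKZF1-ko had more mRNA of the macrophage receptor genes TREM2 (7.28-fold), CSF1R (4.07-fold) and CX3CR1 (4.04-fold), and less mRNA of GATA2, a transcription factor of blood progenitors (1.95-fold lower), and of the endoplasmic reticulum chaperone CALR (1.74-fold lower). Of the genes listed for each, 10 of 13 heat shock genes and 8 of 19 genes of the endoplasmic reticulum unfolded protein response fell. Of 23 p53 target genes, 8 fell and 1 rose. Among those that fell was CDKN1A, an inhibitor of cyclin-dependent kinases, which fell by 0.67 on the log2 scale. CDK4, CDK6, BCL2 and MCL1 did not pass the test. These values come from an edgeR fit with a term for the library set, chosen after the data were seen. That fit had 862 of 13028 genes falling. With a surrogate variable in place of the term, CDKN1A fell by 0.45 and the median of the p53 targets was -0.115 in place of -0.23. When the correlation between genes was estimated, 0 of 35 gene lists passed the list test. The planned edgeR fit on group alone called 0 of 13028 genes, and in it 456 genes (3.50%) had an unadjusted p under 0.05. Of the other tools run on group alone, DESeq2 called 59 genes, limma-voom 1, limma-voom with quality weights 407 and edgeR without a filter on low counts 8.

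The libraries fell into sets that cut across the groups. The first principal component of log2 CPM held 67.6% of the variance and set NT control replicate 2 (score 39.5) and IKZF1-ko replicate 1 (score 50.1) apart from the other 4 libraries (scores -29.1 to -16.3). The second component held 14.9% of the variance and separated the groups. NT control replicate 2 was closer to IKZF1-ko replicate 1 (Pearson r across genes 0.988) than to NT control replicate 1 (0.967) or replicate 3 (0.966). No label names a batch, culture day or preparation that these libraries share. Replicates 1 and 3 of NT control and replicates 2 and 3 of IKZF1-ko differed by more than counting noise (chi-square per degree of freedom 2.29 and 2.32), which does not tell separate cultures from repeat extractions of 1 culture. Each library was counted as 1 sample. With a term for the library set beside the group, the coefficient of variation between replicates was 4.83%, against 22.2% on group alone.

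**Figure D1:**
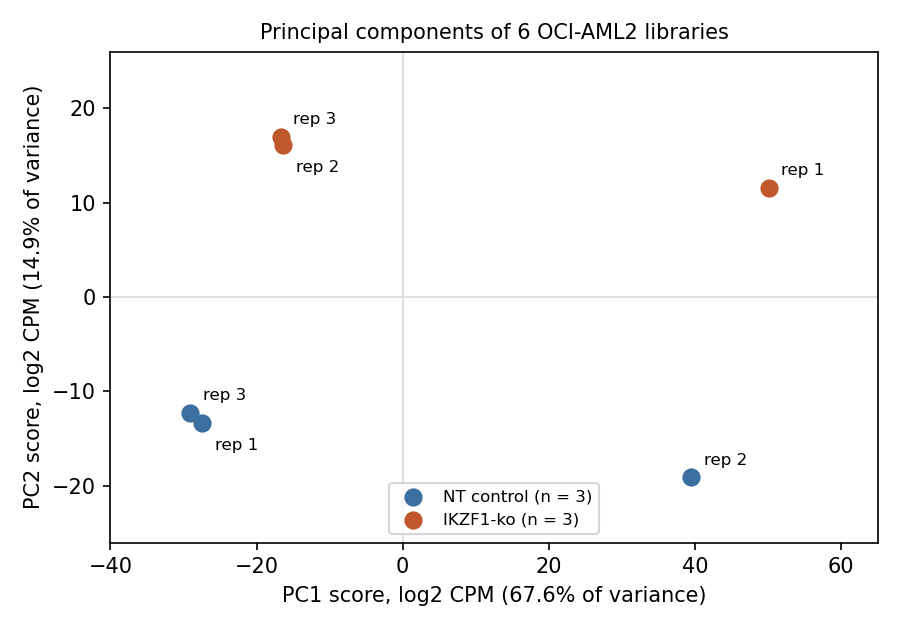
Scores of the 6 libraries on the first (x axis, 67.6% of variance) and second (y axis, 14.9% of variance) principal components of log2 CPM, with 1 point per library, coloured by group (n = 3 each) and marked with its replicate number. NT control replicate 2 and IKZF1-ko replicate 1 lie at 39.5 and 50.1 on the first component, apart from the other 4 libraries.

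With the library-set term, edgeR's quasi-likelihood test called 1765 genes, 903 rising and 862 falling in IKZF1-ko, and 120 of them changed at least 2-fold. Across genes, the fold change of this fit still followed the difference between the sets (Spearman rho 0.359). With a surrogate variable in place of the term rho was 0.01. The term may therefore leave part of the difference between the sets in the group changes. The genes with the largest rise that met the naming rule were CASKIN2, a scaffold protein gene, at 1.12 ± 0.751 CPM in NT control and 8.18 ± 3.15 CPM in IKZF1-ko (SD, n = 3 each; log2 fold change 2.90, SE 0.22, adjusted p = 2.97e-07), and TREM2 (ENSG00000095970, chromosome 6, 41158506 to 41163186), at 3.30 ± 2.24 CPM and 23.1 ± 9.43 CPM (log2 fold change 2.86, SE 0.16, adjusted p = 5.39e-09). The small GTPase gene RAB13 rose from 2.70 ± 0.623 to 13.3 ± 1.245 CPM, the kinase gene CDK18 from 3.47 ± 1.90 to 16.3 ± 8.43 CPM, and CSF1R (ENSG00000182578, chromosome 5, 150053291 to 150113372), the receptor of macrophage colony-stimulating factor, from 3.24 ± 1.72 to 12.9 ± 4.62 CPM. The fractalkine receptor gene CX3CR1 rose 4.04-fold, the channel gene CALHM2 3.91-fold, the peroxidase gene LPO 3.73-fold and the cytochrome P450 gene CYP2S1 3.56-fold. The small heat shock protein gene HSPB7 (3.35-fold), the Wnt secretion gene WLS (3.31-fold) and SEZ6L2 (3.25-fold) completed the 12 genes named by rise. RAB13 shares exon positions with another annotated gene on its strand, and WLS, LPO and CALHM2 with genes on the opposite strand, so their values are uncertain where the counting did not tell these apart.

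Of the genes that met this rule, RHEX, a gene of erythroid expansion, had the largest fall, from 5.75 ± 2.21 to 1.81 ± 1.29 CPM (log2 fold change -1.70, SE 0.24, adjusted p = 1.43e-04), and shares exon positions with another gene on its strand. NCF1, which encodes a subunit of the phagocyte NADPH oxidase, was 2.40-fold lower, a value that is uncertain because the near-identical copies NCF1B and NCF1C can share its reads. The aldo-keto reductase gene AKR1C3 was 2.30-fold lower. GATA2 (ENSG00000179348, chromosome 3, 128479427 to 128493185) fell from 22.7 ± 5.17 to 11.7 ± 3.39 CPM (log2 fold change -0.97, SE 0.096, adjusted p = 3.79e-06). CALR (ENSG00000179218, chromosome 19, 12938578 to 12944489) fell from 1810 ± 185 to 1042 ± 118 CPM (log2 fold change -0.80, SE 0.042, adjusted p = 1.47e-09). The other genes named by fall were GAPT (1.93-fold lower), the tetraspanin gene CD82 (1.88-fold), the sphingosine 1-phosphate receptor gene S1PR3 (1.86-fold), the thrombospondin gene THBS1 (1.85-fold), the chemokine gene CXCL8 (1.83-fold), LRG1 (1.72-fold) and TENT5A (1.60-fold). The naming rule asked for non-overlapping groups, which 9.35% of all tested genes had, against 10% by chance for 3 against 3.

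**Figure D2:**
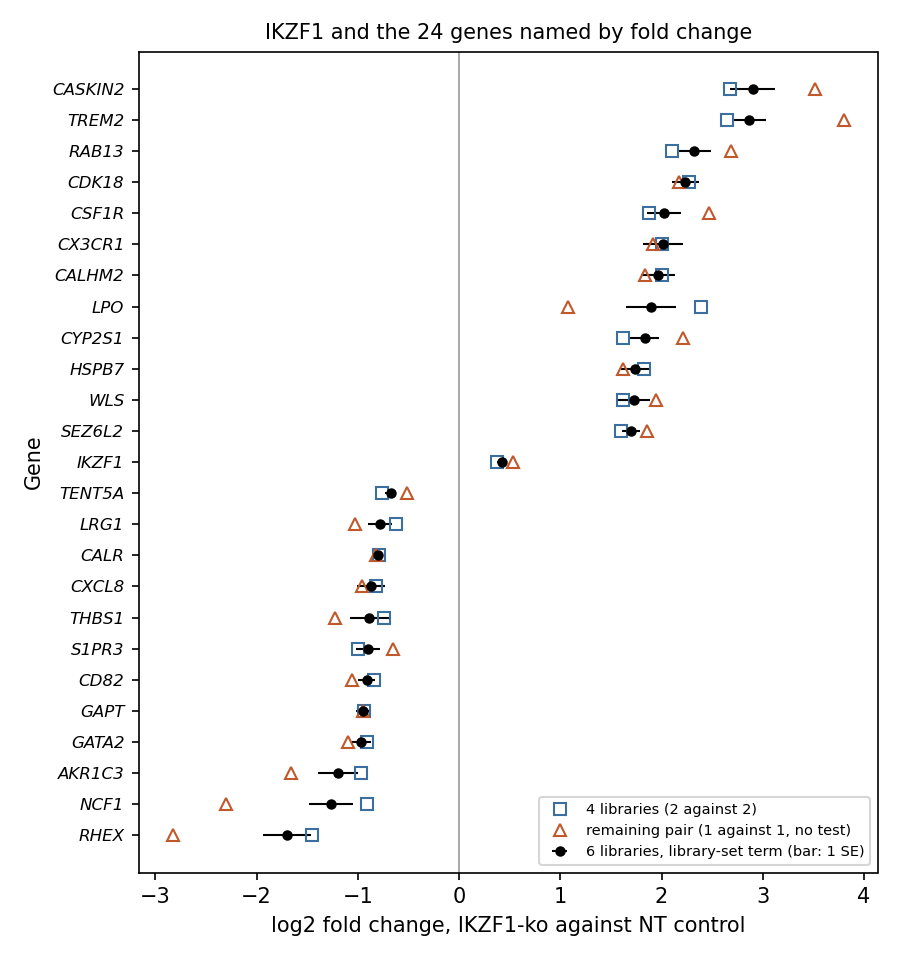
Log2 fold change of IKZF1-ko against NT control (x axis) for IKZF1 and the 24 genes named by fold change (y axis), from the 6 libraries with the library-set term (filled circles, bars of 1 SE), from 4 libraries alone (squares, 2 against 2) and from the remaining pair of 1 library per group (triangles, no test). TREM2 has the highest value in the pair, at 3.80. The genes were chosen for groups that do not overlap, so the pair has the sign of the fit by that choice.

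The comparison was also made within each library set. In the 4 libraries of the larger set, 2 against 2, edgeR called 1908 genes, 989 rising and 919 falling, and 1331 of the genes called with the library-set term were among them. In this set both IKZF1-ko libraries had more counts (18214328 and 16751839) than both NT control libraries (11699047 and 11300519). Depth thus went with the group there, and its part in these calls was not tested. The smaller set holds 1 library per group and gives a difference without a test. An edgeR interaction of set and group called 295 genes, but its spread comes from the larger set alone, so whether the group difference depends on the set is not settled by it. Of 1902 genes called in the 4 libraries and measured in that pair, 1592 (83.7%) had the same sign there, against 63.0% of all genes. Without NT control replicate 1 the fit with the library-set term called 948 genes, and without IKZF1-ko replicate 3 it called 811.

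Gene lists fixed from the study's labels were tested with camera, a test of whether a list moves more than other genes. Of 39 lists, 35 had enough measured members. With the preset correlation, 8 lists passed on group alone and 14 with the library-set term, 6 upward and 8 downward, whereas with an estimated correlation 0 lists passed in these fits, in the 4 libraries alone or with a surrogate variable. The member counts that follow are from the edgeR fit with the library-set term, over all genes and adjusted over the list alone. On group alone, 0 members of any list were called over all genes. Adjusted over the list alone, 5 monocyte and macrophage, 3 granulocyte and 3 mast cell and basophil genes were called on group alone, 1 in each of 9 other lists and 0 in the rest.

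Of 21 measured monocyte and macrophage genes, 7 rose and 3 fell (10 and 4 adjusted over the list alone). CSF1R, CX3CR1 and the calprotectin subunit gene S100A9 (24.1 ± 2.51 to 39.6 ± 2.63 CPM, adjusted p = 3.37e-05) rose, and MNDA, a nuclear antigen gene of myeloid cells, fell by 0.54 on the log2 scale. The list passed camera upward (adjusted p = 0.027, and 0.38 with an estimated correlation). Of 7 dendritic cell genes, 3 rose and 0 fell, the same adjusted over the list alone, and camera gave an adjusted p of 9.16e-04 (0.24 with an estimated correlation). They were NRP1 (8.29 ± 4.17 to 17.5 ± 6.66 CPM), the interleukin 3 receptor gene IL3RA (log2 fold change 0.54, but 0.39 and adjusted p = 0.091 with a surrogate variable) and the lectin gene CLEC10A. CLEC10A had 0 counts over the NT control libraries and 89 over the IKZF1-ko libraries, at least 22.4-fold higher when set against a floor of 3 counts over the group. The list median was 0.32 on the log2 scale, also with CLEC10A at that bound. Without CLEC10A the median of the other 6 genes was 0.26 and camera gave an adjusted p of 0.019. Of 22 myeloid transcription factor genes, 6 rose and 0 fell (10 and 0 adjusted over the list alone), among them ID3 (log2 fold change 0.69), ID1 (0.94, not passing in the 4 libraries, adjusted p = 0.071), FLI1 (0.27) and MEF2C (0.25), with a camera adjusted p of 0.016 (0.40 with an estimated correlation).

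Granule genes moved both ways. Of 13 measured granulocyte genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone, 5 and 5 in the 4 libraries, 2 and 4 with a surrogate variable), and the list did not pass camera (adjusted p = 0.60). The neutrophil serine protease genes ELANE (121 ± 67.6 to 198 ± 77.2 CPM, adjusted p = 1.11e-06) and CTSG (261 ± 26.1 to 394 ± 17.6 CPM, adjusted p = 2.34e-06) rose, and the ribonuclease gene RNASE2 (194 ± 13.1 to 144 ± 26.8 CPM) and the transcription factor gene CEBPE (43.6 ± 1.29 to 29.8 ± 4.31 CPM) fell. Of 4 measured mast cell and basophil genes, 3 fell and 0 rose, the same adjusted over the list alone. They were GATA2, the proteoglycan gene SRGN (3470 ± 215 to 2509 ± 245 CPM) and the histidine decarboxylase gene HDC (1.76 ± 0.436 to 0.276 ± 0.103 CPM). The list was too short for camera. Of 13 stem and progenitor genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone, 2 and 3 in the 4 libraries, 1 and 4 with a surrogate variable), with FLT3 (log2 fold change 0.24) among the first and GATA2, CD38 (-0.37) and MYB (-0.22) among the second, and camera gave an adjusted p of 0.74.

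Heat shock genes fell in 10 of 13 measured members, with 0 rising (12 and 0 adjusted over the list alone), and 13 fell in the 4 libraries and 7 with a surrogate variable, and camera gave an adjusted p of 2.1e-06 (0.24 with an estimated correlation). HSPH1 (192 ± 49.5 to 151 ± 33.8 CPM), HSP90AA1 (1593 ± 525 to 1266 ± 344 CPM), DNAJA1 (log2 fold change -0.31) and HSPB1 (-0.31) had the lowest adjusted p. Of 19 genes of the endoplasmic reticulum unfolded protein response, 8 fell and 0 rose, the same adjusted over the list alone and with a surrogate variable (8 and 3 in the 4 libraries), with a camera adjusted p of 7.99e-04 (0.24 with an estimated correlation). CALR led them, with HYOU1 (log2 fold change -0.42), PDIA4 (-0.38) and HSPA5 (431 ± 120 to 326 ± 62.7 CPM, log2 fold change -0.38). Of 23 p53 target genes, 8 fell and 1 rose (11 and 1 adjusted over the list alone), with a camera adjusted p of 1.57e-04 (0.24 with an estimated correlation). In the 4 libraries 10 fell and 2 rose. With a surrogate variable 7 fell and 0 rose, and the list median was -0.115 in place of -0.23 (camera adjusted p = 0.0086). CDKN1A (62.3 ± 27.8 to 40.2 ± 21.98 CPM, log2 fold change -0.67, SE 0.078, adjusted p = 2.16e-05), AEN (-0.55), MDM2 (-0.38) and the pro-apoptotic gene BAX (-0.36) fell. With the surrogate variable the falls were smaller, at -0.45 for CDKN1A, -0.45 for AEN, -0.31 for MDM2 and -0.19 for BAX. In NT control replicate 2 and IKZF1-ko replicate 1, the libraries that stood apart, the mean log2 level of the heat shock genes was -0.17 and -0.34. It was 0.28 and 0.28 in NT control replicates 1 and 3, and -0.03 and -0.02 in IKZF1-ko replicates 2 and 3. For the unfolded protein response genes these levels were -0.07 and -0.27, 0.17 and 0.19, and 0.003 and -0.02. In both lists NT control replicate 2 lay below IKZF1-ko replicates 2 and 3, so the groups overlapped. The mean log2 level of the p53 target genes, relative to the 6 libraries, was -0.26 in NT control replicate 2 and -0.57 in IKZF1-ko replicate 1, against 0.11 to 0.32 in the other 4 libraries.

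**Figure D3:**
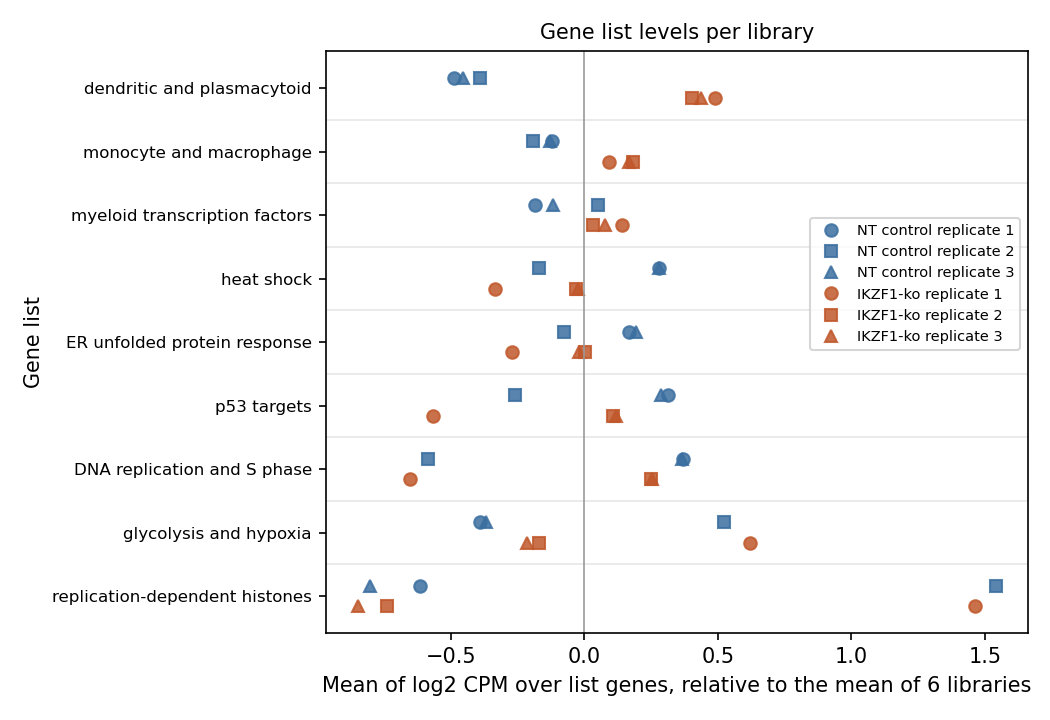
Mean log2 CPM of the genes of 9 lists in each library, relative to the mean of the 6 libraries (x axis), with 1 symbol per library, coloured by group and shaped by replicate number. The dendritic cell genes lie from -0.49 to -0.39 in NT control and from 0.41 to 0.49 in IKZF1-ko, a mean that CLEC10A, with 0 counts in NT control, widens (without it -0.252 to -0.138 and 0.18 to 0.218). The replication-dependent histone genes lie at 1.54 in NT control replicate 2 and 1.46 in IKZF1-ko replicate 1 and from -0.85 to -0.62 in the other 4 libraries.

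Genes tied to the drugs of the study were examined by list. Of 23 measured genes of CDK4, CDK6 and G1 control, 1 rose and 3 fell, the same adjusted over the list alone, and camera gave an adjusted p of 0.22. The cyclin gene CCND3 rose (log2 fold change 0.23, SE 0.051, adjusted p = 0.0072). CDKN1A, E2F4 (-0.20) and the cyclin gene CCNA2 (-0.22) fell. In the 4 libraries alone 1 rose and 6 fell, and the list passed camera downward (adjusted p = 0.021, but not with an estimated correlation). With a surrogate variable in place of the library-set term 1 rose, CCND3 (0.44), and 1 fell, CDKN1A (-0.45). E2F4 (-0.06) and CCNA2 (-0.15) did not pass in that fit, and camera gave an adjusted p of 0.93. CDK4 was at 197 ± 32.6 and 182 ± 38.9 CPM (log2 fold change -0.13, adjusted p = 0.10), CDK6 at 366 ± 7.98 and 348 ± 19.7 CPM (-0.07, adjusted p = 0.32) and RB1 at 127 ± 4.32 and 138 ± 3.17 CPM (0.12, adjusted p = 0.12). Of 5 measured anti-apoptotic BCL2 family genes, BCL2L2 rose (20.1 ± 4.15 to 26.02 ± 4.73 CPM, log2 fold change 0.37, adjusted p = 0.0059), a value that is uncertain because a readthrough gene shares its exons on the same strand. BCL2 (331 ± 15.7 and 336 ± 9.29 CPM, adjusted p = 0.80), MCL1 (214 ± 21.1 and 223 ± 15.8 CPM, adjusted p = 0.48), BCL2L1 (adjusted p = 0.84) and BCL2A1 (adjusted p = 0.063) did not pass, and BCL2A1 passed adjusted over the list alone, where 1 gene rose and 1 fell. Of 10 pro-apoptotic members, 2 rose and 3 fell, the same adjusted over the list alone. BAX fell from 120 ± 44.3 to 94.5 ± 39.9 CPM (log2 fold change -0.36, adjusted p = 2.67e-04), with BCL2L11 (-0.22) and BID (-0.20), and BNIP3L (0.16) and BNIP3 (0.20) rose. In the 4 libraries alone and with a surrogate variable, 0 rose and 2 fell, BAX and BCL2L11, and under RLE scaling 0 rose and 3 fell. BNIP3, BNIP3L and BID did not pass in the 4 libraries (adjusted p = 0.13, 0.14 and 0.12). With the surrogate variable the log2 fold change was -0.19 for BAX, -0.27 for BCL2L11, -0.06 for BNIP3 and 0.02 for BNIP3L. The 2 BCL2 family lists did not pass camera (adjusted p = 0.74 and 0.65).

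The lists of DNA replication, glycolysis and hypoxia, MYC targets and ribosomal proteins had small changes that ran along the difference between the library sets. Most other lists that passed camera with the library-set term, the p53 targets among them, also changed in the direction of that difference. Of 30 DNA replication genes, 7 fell and 1 rose (11 and 2 adjusted over the list alone), with PCNA falling by 0.28 on the log2 scale and CDT1 rising by 0.28, and camera gave an adjusted p of 7.99e-04 (0.24 with an estimated correlation). Their mean level was -0.59 in NT control replicate 2 and -0.65 in IKZF1-ko replicate 1, against 0.25 to 0.37 in the other 4 libraries. Of 27 genes of glycolysis and hypoxia, 8 rose and 1 fell (12 and 2 adjusted over the list alone), led by the glucose transporter gene SLC2A3 (37.1 ± 26.5 to 61.4 ± 41.1 CPM, log2 fold change 0.74, adjusted p = 9.88e-07), with a camera adjusted p of 0.016 (0.40 with an estimated correlation). Their mean level was 0.52 in NT control replicate 2 and 0.62 in IKZF1-ko replicate 1, against -0.39 to -0.17 in the other 4 libraries. Of 28 MYC target and ribosome biogenesis genes 6 fell and 0 rose (10 and 0 adjusted over the list alone), and of 36 ribosomal protein genes 6 rose and 0 fell, the same adjusted over the list alone. Camera gave adjusted p values of 0.0033 and 0.0051 (0.70 and 0.79 with an estimated correlation). With a surrogate variable in place of the library-set term, the replication, glycolysis, MYC target and ribosomal protein lists did not pass camera (adjusted p = 0.51, 0.93, 0.67 and 0.71), and the medians of the first 2 changed sign (0.02 and -0.01). In that fit 2 replication genes rose and 0 fell, 3 glycolysis genes rose and 0 fell, and 0 MYC target and 0 ribosomal protein genes were called. In the 4 libraries alone the MYC target list did not pass either (adjusted p = 0.16), while 20 ribosomal protein genes rose there (camera adjusted p = 7.66e-06). The median of the ribosomal protein genes was 0.123 in the 4 libraries but -0.038 in the remaining pair.

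Of 26 genes of mitosis, 5 fell and 0 rose (6 and 0 adjusted over the list alone), among them PLK1 (log2 fold change -0.27) and BIRC5 (-0.26), with a camera adjusted p of 9.16e-04 (0.57 with an estimated correlation). In the 4 libraries alone 13 fell, and with the surrogate variable 2 fell. Their mean level was -0.247 in NT control replicate 2 and -0.268 in IKZF1-ko replicate 1, against 0.042 to 0.22 in the other 4 libraries. Of 32 nuclear genes of oxidative phosphorylation, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with NDUFA2 falling from 35.03 ± 2.16 to 25.8 ± 3.30 CPM, and camera gave an adjusted p of 1.89e-04 (0.40 with an estimated correlation). With the surrogate variable 2 of them fell (camera adjusted p = 9.8e-04). Of 23 cholesterol synthesis genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone, 8 and 0 in the 4 libraries, 5 and 0 with a surrogate variable), with FDPS falling from 264 ± 21.5 to 217 ± 4.1995 CPM and a camera adjusted p of 0.043 (0.60 with an estimated correlation). Of 23 interferon response genes, 5 rose and 2 fell, the same adjusted over the list alone (4 and 2 in the 4 libraries, 3 and 1 with a surrogate variable). OAS3 rose from 7.56 ± 4.36 to 15.6 ± 9.09 CPM, IRF1 fell from 12.2 ± 4.06 to 7.90 ± 1.90 CPM, and camera gave an adjusted p of 0.043 (0.40 with an estimated correlation), but 0.055 under upper-quartile scaling. With a surrogate variable in place of the library-set term, the mitosis and interferon lists did not pass camera (adjusted p = 0.095 and 0.053). Of 22 genes of ATF4 and amino acid stress, 3 rose with the library-set term and 16 rose in the 4 libraries alone, 0 fell in either, and the median difference in the remaining pair was -0.31. In the fit with the library-set term 7 rose adjusted over the list alone and camera gave an adjusted p of 0.10. The list passed camera upward in the 4 libraries alone (adjusted p = 1.66e-10) and with the surrogate variable (0.0018), where 5 rose, but in neither with an estimated correlation.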

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

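The fits with the library-set term, the 4 libraries alone, the surrogate variable and quality weights were chosen after the data were seen, and the other alternatives to the planned fit were planned. On group alone, 0 genes were called under TMM, RLE, upper-quartile and library-size scaling, with at least 1 CPM in 3 libraries, by glmTreat, and with each library left out in turn (0 to 0 genes). Without a filter on low counts 8 genes were called, all rising and at least 2-fold. DESeq2 called 59 (50 rising, 9 falling, 39 at least 2-fold), limma-voom 1, rising and at least 2-fold. The cause was not tested. The library-set term gave 1765 (903 rising, 862 falling, 120 at least 2-fold), the 4 libraries 1908 (989, 919 and 145), the surrogate variable 1047 (574, 473 and 110) and quality weights 407 (279, 128 and 104). IKZF1 passed the threshold under these, with log2 fold changes of 0.43, 0.37, 0.44 and 0.38 against 0.42 on group alone, and had 0.36 to 0.46 with each library left out.

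Replicate numbers do not pair the samples: deviations from the group means correlated at -0.66 for replicate 1, -0.69 for replicate 2 and 0.59 for replicate 3. The replicate block called 0 genes and 8 lists, and IKZF1 had a log2 fold change of 0.43 under it. The 8 lists were the same as on group alone.

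For the fit with the library-set term, DESeq2 called 1061 genes (479 rising), the surrogate variable 1047 (574 rising, 473 falling) and the fit without the term 0 (0 rising, 0 falling, 0 at least 2-fold). Of the genes called with the term, 1049 were also called by DESeq2 and 930 with the surrogate variable. Tested against a fold of 1.5, 57 genes passed in place of 120. With each library left out, 811 to 1943 genes were called (464 to 1020 rising, 347 to 923 falling). The lowest counts were without IKZF1-ko replicate 3 (811) and without NT control replicate 1 (948). Under the other scalings, filters and limma-voom 1639 to 1996 genes were called. The rising share was 45.15% to 57.21% over all fits with calls, DESeq2 and the libraries left out included. Under other scalings the median of all genes moved by no more than 0.01 on the log2 scale.

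The 24 genes named by fold kept the call in the fit with the library-set term under the other scalings, filters, DESeq2 and limma-voom, with each library left out, in the 4 libraries and with the surrogate variable. Against a fold of 1.5, 17 of them passed, and NCF1, AKR1C3, S1PR3, THBS1, CXCL8, LRG1 and TENT5A did not. On group alone edgeR called 0 of the 24, edgeR without a filter 4, DESeq2 16, limma-voom 0 and quality weights 24. These genes were chosen for their fold and separation in the same libraries, so these counts do not test them independently. Of 124 named genes called with the term, 109 kept the call under DESeq2, 91 with the surrogate variable and 112 in the 4 libraries. Of the called genes that the text names, those that lost the call with the surrogate variable were MTA2, HDAC2, RBBP7, GATAD2A, CCNA2, E2F4, PCNA, BNIP3, BNIP3L, BID, HOXA9, PRF1, IL3RA, HLA-E, ACTA2 and SLC29A1, and in the 4 libraries MTA2, BNIP3, BNIP3L, BID, HOXA9, ID1, HLA-C, ACTA2, ABCC4 and SLC29A1. BNIP3 turned from 0.20 to -0.064 with the surrogate variable, and the cause was not tested.

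Camera called 8 lists on group alone, 14 with the library-set term, 15 in the 4 libraries and 10 with the surrogate variable. With an estimated correlation it called 0 in each of these 4 fits, and fry called 2 on group alone and 9 with the term. The list medians kept their sign under all 4 scalings except that of the NuRD complex (-0.004 to 0.014). Depth limits genes near 1 CPM, such as HDC and CLEC10A.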

Other observations

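Other gene groups, in the edgeR fit with the library-set term chosen after the data were seen, had changes in single members. SPARC, a matricellular protein gene listed among fibroblast genes, rose from 78.0 ± 9.53 to 144 ± 8.73 CPM (SD, n = 3 each; adjusted p = 1.35e-08), and the growth factor receptor gene PDGFRB from 21.2 ± 12.98 to 30.6 ± 18.4 CPM, and ACTA2 fell (-0.78, adjusted p = 0.048, not passing in the 4 libraries or with the surrogate variable). Of the 5 measured genes of that list 2 rose and 1 fell, and camera gave an adjusted p of 0.66. Of 16 adhesion and migration genes 4 rose and 4 fell (6 and 6 adjusted over the list alone, 6 and 4 in the 4 libraries, 5 and 5 with the surrogate variable). The chemokine receptor genes CCR2 (log2 fold change 0.57) and CCR1 (0.39) rose, and the integrin gene ITGA4 (-0.39) and CXCR4 (-0.38) fell. Of 17 genes of NF-kB and inflammatory cytokines 3 rose and 4 fell, the same adjusted over the list alone, with CXCL8 (-0.87) and CCL5 (-0.33) falling and IL1RN (0.42) rising. DUSP6, a phosphatase gene of RAS-MAPK feedback, rose (54.6 ± 5.69 to 71.8 ± 3.96 CPM) and was the 1 gene called of 19 in its list, where 4 rose in the 4 libraries. The transferrin receptor gene TFRC fell (346 ± 112 to 274 ± 92.6 CPM), CD4 rose (191 ± 51.9 to 235 ± 57.5 CPM), and VSIR was the 1 checkpoint gene called of 12 (log2 fold change 0.47, adjusted p = 0.018, with 2 called in the 4 libraries).

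Of 8 drug transporter genes, ABCC1 (log2 fold change 0.19) and ABCC4 (0.20) rose and the nucleoside transporter gene SLC29A1 (-0.17) fell. SLC29A1 did not pass in the 4 libraries or with the surrogate variable (adjusted p = 0.072 and 0.20), nor ABCC4 in the 4 libraries (0.061). Of 13 NuRD complex genes, partners of Ikaros in chromatin, HDAC2 (0.15) rose and MTA2 (-0.17), RBBP7 (-0.16) and GATAD2A (-0.16) fell. With the surrogate variable 0 NuRD genes were called (adjusted p = 0.078, 0.42, 0.14 and 0.61 for these 4). Of 15 MHC class I pathway genes 1 rose (HLA-E, 0.21) and 2 fell (HLA-C, -0.17, and CALR). HLA-E did not pass with the surrogate variable (0.066, adjusted p = 0.54), where 0 rose and 4 fell, nor HLA-C in the 4 libraries (adjusted p = 0.083), where 3 rose and 1 fell. Of 5 MHC class II genes 0 were called, while CD74 rose in the 4 libraries (0.148, adjusted p = 0.030), and of 8 HOXA cluster genes HOXA9 rose (0.25), while 0 were called in the 4 libraries or with the surrogate variable. Of 7 B lymphoid genes 0 were called, of 5 T and NK genes CD4 rose and PRF1 fell (not passing with the surrogate variable, adjusted p = 0.13), and of 6 megakaryocyte genes TREML1 rose and THBS1 fell. The 1 measured gene of the epithelial list, CLDN7, rose from 0.887 ± 0.619 to 2.79 ± 0.825 CPM. Of 13 mitochondrially encoded genes MT-ND6 fell (-0.19; 2 fell in the 4 libraries), and of 9 replication-dependent histone genes 0 were called, though with the surrogate variable that list passed camera downward (adjusted p = 0.0056, but not with an estimated correlation).

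Of the tests below, those of whether the 4 libraries alone carry the changes and of exchanged labels were chosen only after their result was seen, as was the test of the sign of the cholesterol list. The test of hypoxia targets was chosen after the glycolysis and hypoxia list had been seen to differ between the sets. All fits with the library-set term and the surrogate variable were also chosen after the data were seen. NT control replicate 2 and IKZF1-ko replicate 1 departed from the other libraries of their group in the same genes, with r = 0.824 across 13028 genes. After quadratic trends in GC content and length were removed r was 0.83, which argues against those biases. The largest median shift of an autosome present in both was 0.103 on the log2 scale (chromosome 19). This argues against a copy number difference of a whole autosome in most cells. Differences in part of a chromosome or in few cells could not be seen by this median. Of 27 measured targets of the hypoxia-inducible factors, 26 (96.3%, exact 95% interval 81.0 to 99.9) lay above the other libraries of their group in both, against 37.5% of all genes. Of the 12 that are in none of the lists 12 did. The interval takes the targets as independent, but they share regulators and were read in the same 2 libraries, so it does not measure the spread between libraries. So a culture state of low oxygen may be shared by these libraries, by the 96.3% above. These targets do not speak to a state of low nutrients, which was not tested apart from low oxygen. The mean log2 level of the ATF4 and amino acid stress genes was lower in these libraries (-0.29 and -0.553, against 0.037 to 0.377 in the other 4 libraries). The replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, were high there (1.54 and 1.46 on the log2 scale against -0.85 to -0.62). A shared preparation day or batch was not tested and stays open, since the labels give none.

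The second pattern is that edgeR called 0 genes on group alone (456 at an unadjusted p under 0.05) and 1765 with the library set in the model. Calls were also made on group alone by DESeq2 (59), limma-voom (1), edgeR without a filter on low counts (8) and quality weights (407), and with a surrogate variable (1047). Of the genes called in the 4 libraries, 83.7% had the same sign in the pair left out, against 63.0% of all genes. Exchanged labels of the pair would reverse most of these signs, but that test was chosen after its result was seen. Whether the 4 libraries alone carry the changes, or the labels of the pair were exchanged, is not settled by this share. The bound set for both tests lay under the share of all genes. IKZF1-ko also lay toward the smaller set within both sets (by 0.119 and 0.125 on the surrogate variable). Position along that axis can thus give the same sign in the pair. Among the 10 splits of the 6 libraries into 3 and 3, the real split gave 1765 genes with the term and the highest other split 0 (1 of 10 splits as large), and for genes changed at least 2-fold 120 and 0 (1 of 10). On group alone all 10 splits gave 0 genes, also at 2-fold (10 of 10 in both). With 10 splits no share under 0.05 can be had. Whether edited and control lines differed in ways other than IKZF1, such as clonal drift, was not tested, and no biological explanation beyond the group label was tested.

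The third pattern is that lists which differ between the groups also differ between the library sets, so part of the group difference may be a difference in position along that axis. With a surrogate variable, which lets each library take its own position, the ratio of list medians to those with the set term was 0.573 at the median over 13 lists whose set difference has the sign of their group difference (range -0.178 to 0.888), so axis position and genotype cannot be told apart for these lists as a whole, the value lying between the bounds set for either. It was lowest for DNA replication and glycolysis and highest for the dendritic cell list (0.888) and the unfolded protein response (0.818). For cholesterol synthesis, whose set difference has the other sign, position along the axis would act the other way. IKZF1-ko lay toward the smaller set within both sets (by 0.119 and 0.125 on the surrogate variable, the sets being 0.856 apart), which would raise these genes. Their median was -0.095 (bootstrap SD over genes 0.026), below 0 in 17 of 23, the opposite of what axis position would give. That SD takes the genes as independent and leaves out the spread between libraries. As the sign was also known when the test was chosen, no conclusion on axis position is drawn from it. The median was 0.036 in the pair left out, and the list did not pass camera with an estimated correlation. In the splits, lists called on group alone were 8 in the real split and 14 in the highest other (5 of 10 as large), and with the term 14 and 11 (1 of 10), and the 4 splits with NT control replicate 2 and IKZF1-ko replicate 1 on the same side gave 11 to 14 lists on group alone.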
